A study of Mus musculus with 24 samples.

How the data were processed

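Livers of female B6C3F1 mice were used, 4 control and 4 furan animals per the labels, each divided into a fresh-frozen piece and 2 FFPE pieces fixed for 18 h or 3 wk. Per the labels, RNA came from about 100 mg of frozen tissue with a midi column kit, and from 1 section (18 h) or 2 sections (3 wk) of 10 micrometres with an FFPE kit, so preservation cannot be separated from the extraction kit and the number of sections. RNA integrity numbers were above 8.9 for frozen and between 1.3 and 2.4 for FFPE RNA per the labels. Libraries were selected on poly(A), made with an unstranded kit and sequenced on a HiSeq 2000. Per the submitters' processing notes, reads were processed with CASAVA 1.8.2, aligned with STAR 2.3.0 to mouse build mm9 and counted per gene with featureCounts 1.4.4.

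The deposited table holds raw integer counts for 24015 gene symbols. It has 24 columns, of which 22 matched a labelled sample by preservation and animal number, and the treatment was taken from the label. The remaining 2 fresh-frozen columns carry animal numbers that no label gives and were not used here, and fresh-frozen animals 03 (control) and 42 (furan) have no column in the table. The comparisons therefore used 3 control (02, 04, 06) and 3 furan (41, 43, 44) fresh-frozen libraries, and 4 control (02, 03, 04, 06) and 4 furan (41, 42, 43, 44) libraries for each FFPE time. Total counts are those of the table. Genes of the mitochondrial genome have no line in the table, so their share was not analysed here. The pairing of pieces by animal was checked across genes after the group means were removed: fresh-frozen and FFPE 18 h pieces of 1 animal had r from 0.463 to 0.606, and all 6 were most like their own partner. Fresh-frozen and FFPE 3 wk pieces had r from 0.106 to 0.275 (6 of 6), and the FFPE pieces r from 0.00834 to 0.310 (7 of 8). No pair of libraries within a group was a duplicate (lowest chi-square per degree of freedom 9.73).

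Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 on the libraries of its own groups: low counts were filtered with filterByExpr, libraries scaled with TMM, which the mean CPM of a group also uses, and genes tested with the quasi-likelihood F test. Adjusted p is the Benjamini-Hochberg value over all tested genes, with a threshold of 0.05. The difference between furan responses was tested as an interaction of treatment and preservation. Gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, and again with an estimated correlation, over lists with at least 5 tested members. The p53 and NRF2 lists in fresh-frozen and FFPE 3 wk livers, and the p53 and heat shock lists in FFPE 18 h livers, were the calls that held with an estimated correlation. Shares and totals per library were compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3 libraries, 0.0571 for 4 against 3 and 0.0286 for 4 against 4. The fits were tested on simulated data with known changes: at a 2-fold change, 73.8% of changed genes were recovered in the fresh-frozen, 73.1% in the FFPE 18 h and 20.6% in the FFPE 3 wk furan comparison, with false calls making up 7.28%, 2.96% and 3.70% of all calls.

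The comparisons, the gene lists, the rule for the genes named and the first set of alternatives were fixed before the data were examined. For each furan comparison they are the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between groups, and the genes of the fresh-frozen comparison were followed in FFPE livers. For each preservation comparison they are the 8 largest differences each way by the same criteria. Up to 4 members with the smallest p of a discussed list, the genes Cyp2e1, Nqo1, Gstm1, Cdkn1a, Mdm2, Ccnd1 and Alb, and 14 reference genes were added. Folds against a group with 0 counts are lower bounds from 3 counts over the group, and ratios on 1 to 3 counts carry a 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Transcript length, GC content and sequence shared with other genes came from the GENCODE M21 annotation of a later build, matched by symbol or synonym for 23621 of 24015 genes (98.4%). A gene's transcript end was its last 300 nt, counted as shared where it holds 50-nt words of another gene or overlaps one on either strand.

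Common dispersion was 0.0150 in fresh-frozen, 0.0284 in FFPE 18 h and 0.336 in FFPE 3 wk furan comparisons. The first set of alternatives was DESeq2 1.42.0, RLE scaling, no filter on low counts, a filter at 5 CPM, a fold of at least 1.5, robust dispersions, 1 model of all 6 groups, binomial thinning to the shallowest total (3666173 counts), the animal as a block, each library left out in turn, different animals in each preservation and an estimated correlation. Chosen after seeing the data were fits without the libraries with most Rn45s, without the shallowest libraries, without those with most skeletal muscle transcripts, and on the 6 animals used fresh-frozen (the 3 control animals among them in comparisons of control livers) with and without thinning, as well as the omission of each library or animal from the list, correlation and length results. Levels of single libraries, the figures, sums of muscle genes and gaps between samples use CPM of the total counts without TMM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and permutation tests used scipy 1.17.1.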

Results

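Female B6C3F1 mice received 8 mg/kg body weight of furan in corn oil, or corn oil alone, by gavage on 21 days, and livers were taken 4 h after the last dose. Each liver gave 1 fresh-frozen piece and 2 formalin-fixed, paraffin-embedded (FFPE) pieces, fixed for 18 h or for 3 wk. Furan is a volatile liver toxicant that hepatocytes oxidise to a reactive dialdehyde. The replicates of a group are separate animals, named by their numbers, and the pieces of 1 liver share a number. The comparisons below address the transcript response to furan in each kind of piece, and the difference between the kinds of piece in control livers. That difference also holds the extraction kit and the number of sections, which cannot be separated from fixation. Fold changes are fitted log2 values ± SE. The SE is the absolute log2 fold change over the square root of its F statistic. Where 1 group holds few counts, as for Gsta1 in fresh-frozen controls, this SE is approximate and can lie below the counting error. Levels are CPM, scaled with TMM where a group mean is given and to the total counts where single libraries are given. A gene rose, fell or passed only where its adjusted p was under 0.05.

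The ribosomal RNA precursor gene Rn45s and other RNAs without a poly(A) tail took a larger share of the counts in FFPE libraries than in fresh-frozen ones. Rn45s held 0.161% ± 0.0254 (SD, n = 3) of the counts of fresh-frozen control livers, 14.4% ± 15.2 (n = 4) of FFPE 18 h and 6.89% ± 1.96 (n = 4) of FFPE 3 wk control livers. The FFPE 18 h mean rested on control animal 06, at 37.3% (95% Wilson interval 37.28 to 37.33), where the other 3 control libraries lay between 6.42% and 7.22%. Albumin (Alb), the main protein that hepatocytes secrete, held 11.1% of the counts in fresh-frozen control livers, 7.68% in FFPE 18 h and 6.43% in FFPE 3 wk. Histone genes of the kind whose transcripts lack a poly(A) tail held 0.00337%, 0.0109% and 0.0107%, and genes for cytosolic ribosomal proteins held 0.194%, 0.488% and 0.411%. Every one of these differences between fresh-frozen and FFPE control livers reached the smallest p that 3 against 4 libraries allow in an exact two-sided permutation test, p = 0.0571, with an adjusted p of 0.145 over 66 tests. Total counts ran from 33101755 to 58048387 in fresh-frozen, from 16269854 to 22494012 in FFPE 18 h and from 3666173 to 11780691 in FFPE 3 wk libraries. FFPE 3 wk libraries of control livers had fewer counts than FFPE 18 h libraries (exact permutation p = 0.0286, the smallest that 4 against 4 allow, adjusted p = 0.145).

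**Figure D1:**
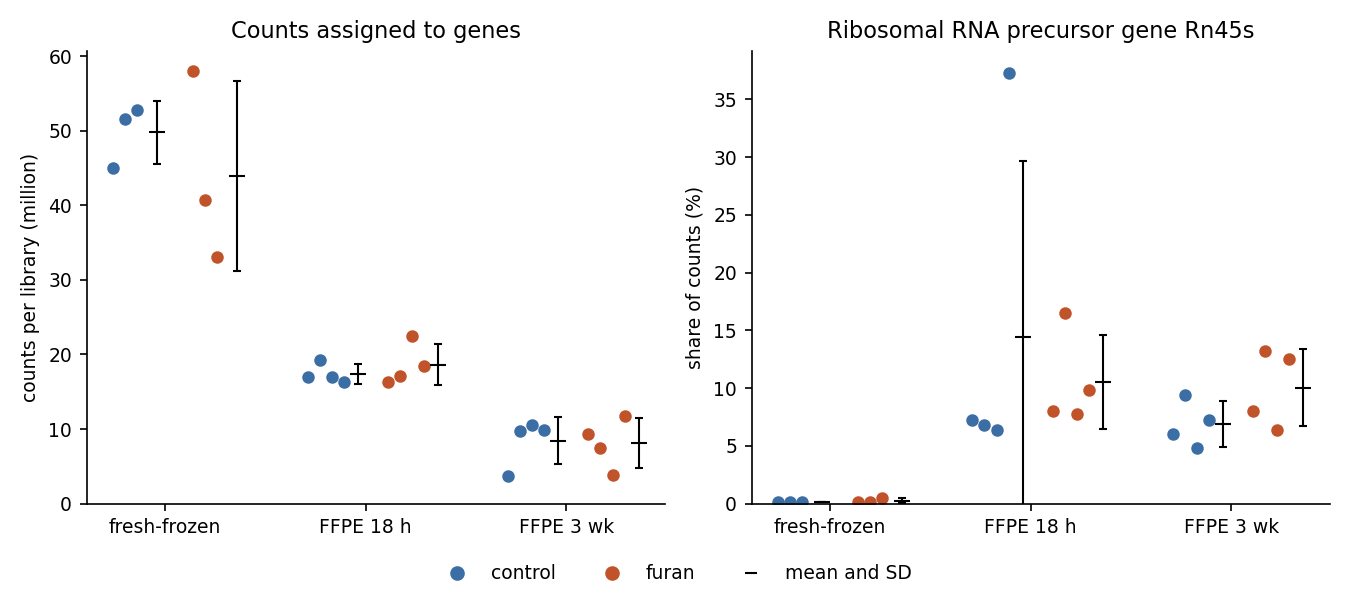
Counts assigned to genes and the share of counts on Rn45s, in percent, for each of the 22 libraries (points), with the mean and SD of each group. Fresh-frozen libraries hold 33101755 to 58048387 counts and at most 0.52% Rn45s, and control animal 06 in FFPE 18 h holds 37.3% Rn45s.

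Among genes of at least 5 CPM in fresh-frozen livers, Cdkn1a, Dusp8 and Eda2r had the largest rises with furan. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose by 4.97 ± 0.10, from 0.843 CPM ± 0.0705 (SD, n = 3) in control to 26.6 CPM ± 1.16 (n = 3) in furan livers. Dusp8, a phosphatase that inactivates stress kinases, rose by 4.79 ± 0.34, and Eda2r, a member of the tumour necrosis factor receptor family, rose by 4.62 ± 0.50. Phlda3, an inhibitor of AKT signalling, rose by 4.21 ± 0.26 and the macrophage elastase Mmp12 by 4.15 ± 0.48. The stress-induced transcription factors Atf3 and Jun rose by 3.08 ± 0.32 and 2.71 ± 0.20. The cytochrome P450 gene Cyp3a16 rose by 3.17 ± 0.71, 4632434I11Rik by 2.88 ± 0.18 and the major urinary protein gene Mup20 by 2.70 ± 0.40. Mup20 belongs to a family of near-identical copies that share reads, so its level is uncertain. B930025P03Rik, named only by its clone, fell by 2.84 on the log2 scale (SE 0.24), Cux2, a homeobox factor higher in female than male liver, by 1.86 (SE 0.42), and Pcp4l1 by 1.71 (SE 0.19). Rad51b, which acts in repair by homologous recombination, fell by 1.62 (SE 0.19), the apoptosis activator Bmf by 1.41 (SE 0.24) and the disintegrin family gene Adam11 by 1.42 (SE 0.21). The other named falls were 1500017E21Rik at -1.86, whose transcript end overlaps a gene on the opposite strand, 4833411C07Rik at -1.69, Ankrd55 at -1.57 and AW549542 at -1.31.

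Of 13794 genes tested in fresh-frozen livers (3 furan, 3 control), 1132 rose and 1030 fell, and 332 of these 2162 changed at least 2-fold. The ranges of furan and control livers did not overlap for 5158 genes, 37.4% of those tested, where chance gives 10%. The count fell to 864 without furan animal 43, 1140 without furan 44, 1287 without control 04, 1311 without control 02 and 1356 without furan 41. It was 138 in 1 model of all 6 groups, where 9 of the 20 named genes (Cyp3a16, Cux2, Ankrd55, Mmp12, Atf3, 4632434I11Rik, 1500017E21Rik, Adam11 and AW549542) did not pass. Cyp3a16, Cux2 and Ankrd55 also did not pass with robust dispersions (adjusted p = 0.0910, 0.0927 and 0.113).

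Target genes of NRF2, the regulator of the antioxidant response, rose as a group in fresh-frozen livers. Of 31 tested, 19 rose and none fell over all genes, and 20 rose and 1 fell adjusted over the list alone. Gsta1, a glutathione transferase with near-identical copies, rose by 5.71 ± 0.31 from 0.0401 CPM. Srxn1, which repairs oxidised peroxiredoxins, rose by 1.42 ± 0.11, the quinone reductase Nqo1 by 1.20 ± 0.10, the epoxide hydrolase Ephx1 by 1.09 ± 0.07 and the glutathione transferase Gstm1 by 0.66 ± 0.09. The list as a whole ranked above other genes (camera adjusted p = 2.82e-23, and adjusted p = 0.0318 with an estimated correlation). Among 22 targets of the tumour suppressor p53, 16 rose and 1 fell, and the counts were the same adjusted over the list alone. Beside Cdkn1a, Eda2r and Phlda3, these included the death receptor Tnfrsf10b at 3.33 ± 0.23, the p53-induced zinc finger gene Zmat3 at 1.74 ± 0.09, and the p53 ubiquitin ligase Mdm2 at 1.02 ± 0.07. The p53 list passed with a preset correlation (adjusted p = 2.21e-60) and with an estimated one (adjusted p = 0.0184).

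Some immediate early, heat shock and cell cycle genes also rose in fresh-frozen livers. Of 17 immediate early genes, 7 rose, 8 adjusted over the list alone, among them Myc, a growth-promoting factor, at 1.99 ± 0.51 and Fosl2, an AP-1 subunit, at 1.17 ± 0.16. The list passed (adjusted p = 1.70e-07), but not with an estimated correlation (adjusted p = 0.196). Among 16 heat shock and metallothionein genes 6 rose, 8 adjusted over the list alone, including the chaperones Hsp90aa1 at 0.82 ± 0.13 and Hsph1 at 0.79 ± 0.13 (list adjusted p = 0.000183, and adjusted p = 0.356 with an estimated correlation). Of 29 cell cycle genes, 15 rose and 1 fell, and 21 rose and 1 fell adjusted over the list alone. The mitotic activator Cdc20 rose by 2.20 ± 0.41, cyclin B2 (Ccnb2) by 2.04 ± 0.33 and the proliferation marker Mki67 by 1.46 ± 0.30, while cyclin D1 (Ccnd1) did not pass (0.14 ± 0.20, adjusted p = 0.679). The cell cycle list passed at adjusted p = 3.58e-10, and not with an estimated correlation (adjusted p = 0.498).

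Oncofetal genes, which are high in fetal liver and in liver tumours, rose in 3 of 8 cases, 4 adjusted over the list alone. The imprinted RNA H19 rose by 1.82 ± 0.26, the Golgi protein gene Golm1 by 1.22 ± 0.19 and Ly6d by 1.96 ± 0.38 (list adjusted p = 0.000242, and adjusted p = 0.356 with an estimated correlation). Among 13 chemokines and NF-kB targets 3 rose and 1 fell, 4 and 1 adjusted over the list alone, with the T cell attractant Cxcl10 at 1.46 ± 0.15 and the adhesion molecule Icam1 at 0.63 ± 0.11 (adjusted p = 0.0263, and adjusted p = 0.651 with an estimated correlation). In the clock list 2 of 18 genes rose and 1 fell, the same adjusted over the list alone, including the activator Arntl at 2.12 ± 0.31, and the list did not pass (adjusted p = 0.534). Of 24 cholesterol synthesis genes, 5 rose and 1 fell, and the counts were the same adjusted over the list alone. The sterol sensor Insig1 rose by 0.58 ± 0.09 and lanosterol synthase (Lss) by 0.61 ± 0.13 (list adjusted p = 0.00533, and adjusted p = 0.758 with an estimated correlation). The cholesterol list did not pass without control animal 04 or furan 41 (adjusted p = 0.128 and 0.0520), nor the chemokine list without control 02 or furan 43 (adjusted p = 0.216 and 0.113).

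Some hepatocyte genes fell in fresh-frozen livers, while other members of their lists did not pass over all genes. Cyp2e1, the P450 enzyme that oxidises furan, fell by 0.97 on the log2 scale (SE 0.11), from 10290 CPM in control to 5263 CPM in furan livers. Of 14 genes of pericentral hepatocytes, the cells around the central vein, 7 fell, 11 adjusted over the list alone, including glutamine synthetase (Glul) at -0.51 ± 0.11 (list adjusted p = 8.44e-06, and adjusted p = 0.498 with an estimated correlation). Genes of the urea cycle and amino acid catabolism fell in 4 of 18 cases, 5 adjusted over the list alone, with ornithine transcarbamylase (Otc) at -0.51 ± 0.08 and proline dehydrogenase (Prodh) at -0.81 ± 0.15 (adjusted p = 0.00150, and adjusted p = 0.651 with an estimated correlation). Among 17 bile acid genes 3 fell and 1 rose, 4 and 1 adjusted over the list alone, with the uptake transporters Slc10a1 at -0.53 ± 0.13 and Slco1b2 at -0.55 ± 0.11 (adjusted p = 0.0387, and adjusted p = 0.651 with an estimated correlation, and 0.171 and 0.111 without control animal 02 or furan 44). Markers of sinusoidal endothelial cells fell in 5 of 12 cases and in all 12 adjusted over the list alone, with the scavenger receptor Stab2 at -0.57 ± 0.10 (adjusted p = 8.94e-06, and adjusted p = 0.498 with an estimated correlation). Xenobiotic P450 genes went both ways, with 3 risen and 7 fallen of 26, or 3 and 9 adjusted over the list alone. Cyp2a4 rose by 1.15 ± 0.15 and Cyp1a2 stood at -0.65 ± 0.15, and the list did not pass (adjusted p = 0.254).

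No member passed over all genes among 18 interferon-stimulated genes, 17 macrophage markers, 9 T and NK cell markers, 7 B and plasma cell markers, 10 stellate cell markers and 15 hepatocyte secreted proteins in fresh-frozen livers (edgeR), and none passed adjusted over the list alone. Alb changed by 0.06 ± 0.14 (adjusted p = 0.792). Of 21 matrix and fibrosis genes 1, the collagenase Mmp13, rose by 2.40 ± 0.63, and 0 rose adjusted over the list alone. Genes commonly used as references did not all hold: RNA polymerase subunit Polr2a rose by 0.88 ± 0.09, Gusb rose by 0.37 ± 0.07 and B2m, the light chain of class I molecules, fell by 0.43 on the log2 scale (SE 0.08). The other 11 of the 14 reference genes did not pass. Among them Gapdh, with 76.67% of its transcript end shared, lay at 1.845 to 4.139 CPM in fresh-frozen libraries. Ppia lay at 0.7781 to 1.208 CPM, so for these low levels not passing does not show stability. Gusb did not pass in 1 model of all 6 groups or after thinning to the shallowest total (adjusted p = 0.0999), and B2m did not pass without furan animal 43 (adjusted p = 0.0558).

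**Figure D2:**
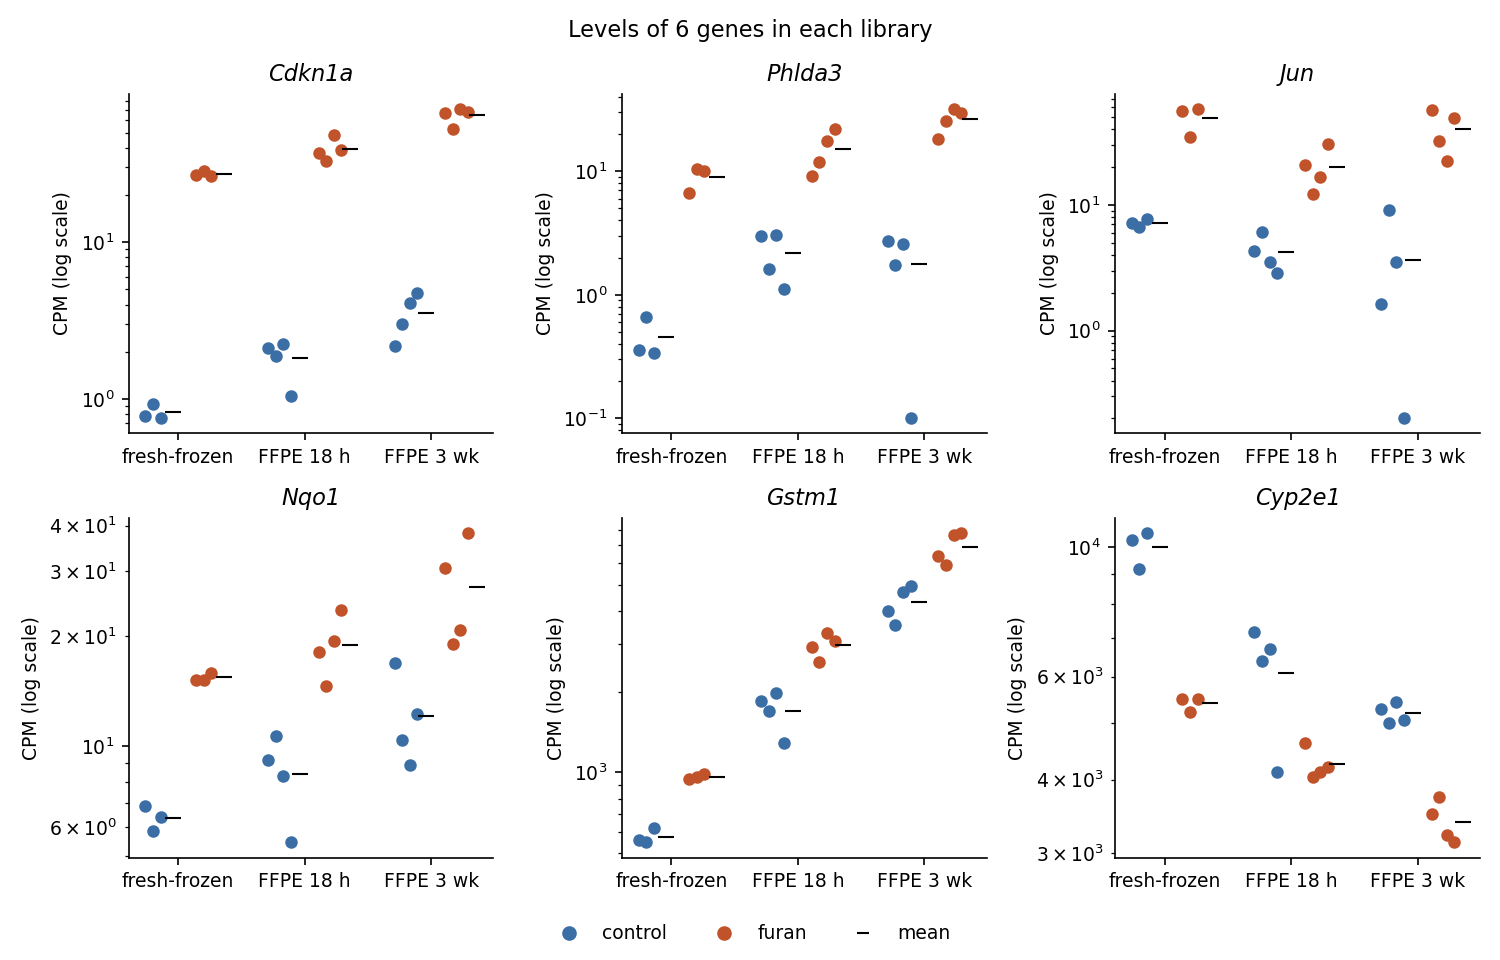
Levels in CPM (log axis) of Cdkn1a, Phlda3, Jun, Nqo1, Gstm1 and Cyp2e1 in each of the 22 libraries (points), with the mean of each group, for the 3 preservations. Scaled to total counts, Cdkn1a in fresh-frozen livers is at most 0.930 CPM in control and at least 26.4 CPM in furan animals.

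In FFPE 18 h livers p53 targets and antioxidant genes were among those that rose. Cdkn1a rose by 4.32 ± 0.14, from 1.84 CPM ± 0.265 (SD, n = 4) to 37.2 CPM ± 4.46 (n = 4), Phlda3 by 2.69 ± 0.29 and Gdf15, a stress-induced circulating cytokine, by 2.48 ± 0.23. Jun rose by 2.14 ± 0.25, Mup20 by 2.23 ± 0.29, Gm11974 by 2.26 ± 0.19, the carbonic anhydrase Car15 by 2.24 ± 0.28 and Tsku, a secreted signalling modulator, by 2.07 ± 0.29. Gm3776 (4.86 ± 0.64) and Gsta1 (3.14 ± 0.42) encode near-identical glutathione transferases, so the split of reads between them is uncertain. The transcript end of Car15 is 99.67% shared with other genes, so its level is uncertain too. B930025P03Rik fell by 2.88 on the log2 scale (SE 0.25), Lect1, a cartilage growth regulator, by 2.36 (SE 0.22), Rad51b by 1.71 (SE 0.15), Pcp4l1 by 1.56 (SE 0.12) and the flagellin receptor Tlr5 by 1.64 (SE 0.35). The remaining named falls were Cpsf4l at -1.68, Ncmap at -1.61, Adam11 at -1.57, the adrenergic receptor Adra1a at -1.49 and the glutamate transporter Slc17a8 at -1.43. Cyp2e1 fell by 0.62 on the log2 scale (SE 0.08), Nqo1 rose by 1.06 ± 0.14, Gstm1 by 0.69 ± 0.07 and Mdm2 by 0.94 ± 0.12, while Ccnd1 and Alb did not pass.

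Of 12832 genes tested in FFPE 18 h livers (4 furan, 4 control), 503 rose and 574 fell, and the groups did not overlap for 2020 genes (15.7%, where chance gives 2.86%). The count of 1077 fell to 633 without furan animal 44 and to 664 without furan 43. It was 697 after thinning, 594 in the 6 animals also used fresh-frozen, and 417 when these were also thinned. In 1 model of all 6 groups it was 225. In that model Gsta1, Car15, Lect1, Cpsf4l, Ncmap, Adra1a and Slc17a8 did not pass, and Tlr5 and Adra1a did not pass in the 6 animals also used fresh-frozen, nor Ncmap when these were also thinned. Of the 20 genes named in fresh-frozen livers, 1500017E21Rik (-1.11 ± 0.47, adjusted p = 0.172) and Cux2 (-0.81 ± 0.52, adjusted p = 0.380) did not pass in FFPE 18 h.

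NRF2 targets rose in 17 of 31 cases in FFPE 18 h, 25 adjusted over the list alone, with Ephx1 at 1.13 ± 0.10 and Srxn1 at 1.39 ± 0.13 (list adjusted p = 7.63e-27, and adjusted p = 0.0541 with an estimated correlation). Targets of p53 rose in 14 of 21 cases, 15 adjusted over the list alone, with the cyclin G gene Ccng1 at 1.12 ± 0.09 and the apoptosis effector Bax at 1.05 ± 0.11 (adjusted p = 2.17e-36, and adjusted p = 0.0115 with an estimated correlation). Heat shock genes rose in 6 of 15 cases, 7 adjusted over the list alone, and passed both tests (adjusted p = 2.22e-05, and adjusted p = 0.0354 with an estimated correlation). Jun and Atf3 were the 2 immediate early genes of 16 that rose, 6 adjusted over the list alone (adjusted p = 0.000101, and adjusted p = 0.164 with an estimated correlation). None of 27 cell cycle genes rose over all genes or over the list alone and 1, thymidine kinase (Tk1), fell by 0.97 on the log2 scale (SE 0.12), though the list's median was 0.53 and it passed as higher (adjusted p = 0.00988, and adjusted p = 0.462 with an estimated correlation, and 0.0645 without furan animal 44). Asns, asparagine synthetase, rose by 2.66 ± 0.50, while its list of ER stress and amino acid response genes did not pass (adjusted p = 0.0771).

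Some hepatocyte genes fell in FFPE 18 h livers, while most members of their lists did not pass over all genes. Genes of the urea cycle and amino acid catabolism fell in 6 of 18 cases, and 7 fell and 1 rose adjusted over the list alone, with Prodh at -0.82 ± 0.12 (adjusted p = 0.00324, and adjusted p = 0.411 with an estimated correlation). Pericentral genes fell in 6 of 14 cases, 6 adjusted over the list alone (adjusted p = 0.000513, and adjusted p = 0.212 with an estimated correlation), and endothelial markers in 3 of 12, 8 adjusted over the list alone, with Stab2 at -0.59 ± 0.09 (adjusted p = 0.000101, and adjusted p = 0.0541 with an estimated correlation). Bile acid genes fell in 4 of 18 cases, and 7 fell and 1 rose adjusted over the list alone (adjusted p = 0.0143, and adjusted p = 0.349 with an estimated correlation). Cholesterol synthesis genes rose in 4 of 24 cases, and 7 rose and 1 fell adjusted over the list alone, with squalene epoxidase (Sqle) at 0.64 ± 0.14 (adjusted p = 0.0154, and adjusted p = 0.659 with an estimated correlation). The fetal serum protein gene Afp rose by 0.96 ± 0.21 as 1 of 8 oncofetal genes, 1 adjusted over the list alone (adjusted p = 0.0176, and adjusted p = 0.439 with an estimated correlation). Of 14 reference genes 1, Polr2a, rose by 0.51 ± 0.09, while 4 rose and 1 fell adjusted over the list alone, and their list passed as higher (adjusted p = 0.0222, and adjusted p = 0.227 with an estimated correlation). Without 1 library the bile acid list (control animal 02, adjusted p = 0.0828), the cholesterol list (control 04, furan 41 or furan 43, 0.131, 0.134 and 0.0919), the oncofetal list (control 06 or furan 43, 0.105 and 0.0583) and the reference list (control 06, 0.0798) did not pass. Polr2a did not pass in 1 model of all 6 groups (adjusted p = 0.133).

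In FFPE 3 wk livers p53 targets were among the genes that rose. Cdkn1a rose by 4.12 ± 0.30, from 3.56 CPM ± 1.19 (SD, n = 4) to 64.0 CPM ± 7.01 (n = 4), Phlda3 by 3.88 ± 0.66, Jun by 3.38 ± 0.69, Mup20 by 2.98 ± 0.30 and Gdf15 by 2.61 ± 0.55. Eda2r had 0 counts in the 4 control libraries and was at least 69.8-fold higher in furan livers, with the floor of 3 counts taken over the group. Prc1, which builds the spindle midzone in dividing cells, had 1 count in control livers, and its ratio was 234 (95% counting interval 41.6 to 9278). Tubb2a, a beta tubulin, rose by 2.51 ± 0.33, the cytokine receptor Tnfrsf12a 4.93-fold and the ciliary gene Fbf1 by 2.15 ± 0.42. Of the Tubb2a transcript 60.5% is shared with other genes. B930025P03Rik fell by 3.05 on the log2 scale (SE 0.51), the protease inhibitor Serpina1e, which has near-identical copies, by 1.89 (SE 0.40) and Pcp4l1 by 1.81 (SE 0.38). Notum, which inactivates Wnt proteins, fell by 1.26 on the log2 scale (SE 0.24), the sterol hydroxylase Cyp46a1 by 1.37 (SE 0.17) and the beta-adrenergic receptor Adrb3 by 1.27 (SE 0.24). The other named falls were Mettl20 at -1.84, Fn3k at -1.63, Inca1 at -1.41 and Apol9b, which shares its end with a near-identical copy, at -1.24. Cyp2e1 fell by 0.64 on the log2 scale (SE 0.09) and Gstm1 rose by 0.66 ± 0.12, while Nqo1 (1.16 ± 0.36, adjusted p = 0.176) and Mdm2 (0.67 ± 0.20, adjusted p = 0.154) did not pass.

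Of 12064 genes tested in FFPE 3 wk livers (4 furan, 4 control), 36 rose and 63 fell, and the groups did not overlap for 1063 genes (8.81%, where chance gives 2.86%). The count of 99 moved with each library left out: 34, 41, 31 and 173 without control animals 02, 03, 04 and 06, and 30, 25, 41 and 17 without furan animals 41, 42, 43 and 44. It was 371 by DESeq2 and 194 without a filter on low counts. In 1 model of all 6 groups it was 2030, with a common dispersion of 0.133 against 0.336 here. In the 6 animals used fresh-frozen it was 19, with 13 risen and 6 fallen. Without the libraries with most muscle transcripts 35 rose and 18 fell, and without the shallowest libraries 9 rose and 3 fell. The excess of falls did not hold in these last fits, which were chosen after seeing the data. Cdkn1a, Mup20 and Cyp46a1 were the 3 of 20 named genes that passed under every alternative run. Gstm1 did not pass in those 6 animals (adjusted p = 0.0877), and neither Gstm1 nor Cyp2e1 passed without the shallowest libraries (adjusted p = 0.190 and 0.0793). Among the genes named in fresh-frozen livers, 1500017E21Rik was not tested in FFPE 3 wk, Cyp3a16 had 0 counts in control livers and was at least 44.3-fold higher in furan livers without passing (adjusted p = 0.105), and Dusp8, Mmp12, Atf3, 4632434I11Rik, Cux2, 4833411C07Rik, Rad51b, Ankrd55, Adam11, Bmf and AW549542 did not pass. Still, furan and control levels did not overlap for Atf3 (0 to 3.435 CPM in control, 11.55 to 14.94 CPM in furan livers), 4833411C07Rik, Rad51b, Bmf and AW549542. They overlapped for Dusp8, Mmp12, 4632434I11Rik, Cux2, Ankrd55 and Adam11.

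NRF2 targets rose in 7 of 31 cases in FFPE 3 wk, and 15 rose and 1 fell adjusted over the list alone. Gclc, the rate-limiting gene of glutathione synthesis, rose by 1.37 ± 0.14 and heme oxygenase (Hmox1) by 2.06 ± 0.31 (list adjusted p = 9.52e-15, and adjusted p = 0.0226 with an estimated correlation). Targets of p53 rose in 6 of 21 cases, 9 adjusted over the list alone (adjusted p = 8.26e-20, and adjusted p = 0.00126 with an estimated correlation). Jun was the 1 immediate early gene of 17 that rose, 5 adjusted over the list alone (adjusted p = 8.42e-08, and adjusted p = 0.0977 with an estimated correlation). Urea cycle and amino acid catabolism genes fell in 3 of 18 cases, 9 adjusted over the list alone, with the glyoxylate enzyme Agxt at -0.78 ± 0.12 and Hpd of tyrosine breakdown at -0.80 ± 0.15 (adjusted p = 6.59e-08, and adjusted p = 0.0977 with an estimated correlation). Pericentral genes fell in 3 of 14 cases, 6 adjusted over the list alone, with Glul at -0.45 ± 0.10 (adjusted p = 3.43e-06, and adjusted p = 0.0977 with an estimated correlation). Of 25 xenobiotic P450 genes Cyp2a4 rose and Cyp2e1 fell, 2 and 3 adjusted over the list alone (adjusted p = 0.0437, and adjusted p = 0.157 with an estimated correlation). In 5 further lists no single gene passed over all genes (edgeR), while each list passed. Bile acid genes (17) were lower, with 5 fallen and 1 risen adjusted over the list alone (adjusted p = 0.00125, and adjusted p = 0.0977 with an estimated correlation), as were 15 lipogenesis genes, with 2 fallen (adjusted p = 0.00281, and adjusted p = 0.201 with an estimated correlation), and 15 hepatocyte secreted proteins, with 3 fallen (adjusted p = 0.000641, and adjusted p = 0.34 with an estimated correlation). Oncofetal genes (6) were higher, with 0 passing adjusted over the list alone (adjusted p = 0.00805, and adjusted p = 0.0977 with an estimated correlation), and so were 22 cell cycle genes, with 1 risen and 1 fallen (adjusted p = 0.0302, and adjusted p = 0.144 with an estimated correlation). The P450 list did not pass without control animal 04 or 06 or without furan animal 42 or 43 (adjusted p = 0.0832, 0.163, 0.0935 and 0.0534).

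The furan response had the same direction in the 3 preservations for nearly all genes that passed in more than 1 of them. Fresh-frozen and FFPE 18 h livers shared 344 genes that rose (41.8 if the comparisons were independent) and 411 that fell (45.6), and 1 gene, Smcr8 of an autophagy complex, rose in the former and fell in the latter (0.32 and -0.36). Fresh-frozen and FFPE 3 wk livers shared 34 genes that rose (3.03 if independent) and 52 that fell (5.20), with 0 in opposite directions. The pieces come from the same animals, so the comparisons are not independent. Other splits of the animals gave a median r of 0.423 (0.143 to 0.519) for the first pair. Their median r was 0.159 for fresh-frozen and FFPE 3 wk, and 0.1195 for FFPE 18 h and FFPE 3 wk. These splits can carry part of the furan difference, so the medians do not measure the agreement from shared animals alone. Of the fresh-frozen genes tested in both, 36.6% also passed in FFPE 18 h and 95.5% had the same sign there, against 75.6% of all genes, and 70.2% of the FFPE 18 h genes passed in fresh-frozen livers. In FFPE 3 wk 4.31% of the fresh-frozen genes passed and 82.9% had the same sign, against 65.0% of all genes, and 86.9% of the FFPE 3 wk genes passed in fresh-frozen livers. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.735 (Spearman's rho 0.671) for fresh-frozen and FFPE 18 h over 12673 genes. It was 0.426 (rho 0.399) for fresh-frozen and FFPE 3 wk over 11980 genes, and 0.392 (rho 0.383) for FFPE 18 h and FFPE 3 wk over 11925 genes. In fits on part of the animals the mean r was 0.519, 0.256 and 0.205 in that order with different animals in each preservation, and 0.628, 0.305 and 0.243 with the same animals. Genes that rose at least 2-fold in fresh-frozen livers had a median of 1.51 there and 1.11 in FFPE 18 h (191 genes), and of 1.45 there and 1.47 in FFPE 3 wk (160 genes).

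**Figure D3:**
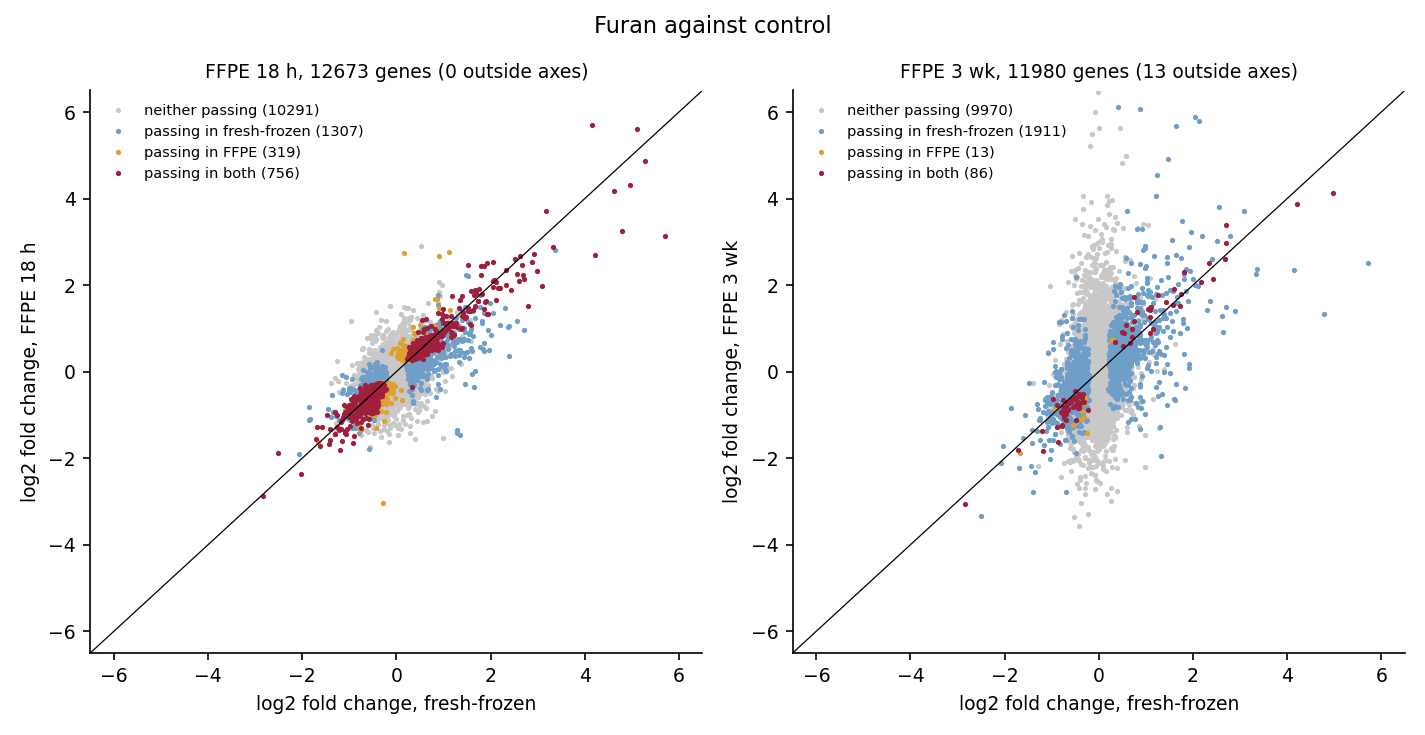
Fitted log2 fold change of furan against control in fresh-frozen livers (x axis) and in FFPE 18 h or FFPE 3 wk livers (y axis), 1 point per gene tested in both, coloured by where adjusted p was under 0.05, with the line of equal change. The 12673 genes of FFPE 18 h lie closer to the line (r = 0.735) than the 11980 genes of FFPE 3 wk (r = 0.426).

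A test of the difference between the furan responses found 0 genes of 13739 for FFPE 18 h against fresh-frozen and 0 of 13156 for FFPE 3 wk against fresh-frozen (edgeR). In this unpaired fit 455 and 590 genes (3.312% and 4.485%) had an unadjusted p under 0.05, where chance gives a share of 0.05. The fit ignores the pairing of pieces by animal, so 0 genes do not show equal responses. Smcr8 had the smallest adjusted p in the first, 0.661, and the interferon-induced GTPase gene Gbp5 in the second, 0.560. DESeq2 found 1 gene, Smcr8, and 38 genes. In the paired fit with the animal as a block the counts were 2, Dmbt1 and the phosphatase regulator Ppp1r10, and 0. In that fit 1559 of 13739 and 741 of 13156 genes had an unadjusted p under 0.05. Both lie above a share of 0.05, the first by far more, unlike in the unpaired fit. Genes are not independent, so these shares are not a test. Without FFPE 3 wk control animal 02 the unpaired edgeR fit gave 5 genes for FFPE 3 wk against fresh-frozen, namely Alg1, Ccdc66, Hgf, Leng9 and Pggt1b. The genes listed by these alternatives were named after their values were seen.

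In control livers, several genes for RNAs without a protein product, such as Rpph1 and Rmrp, were higher in FFPE 18 h than in fresh-frozen pieces, and Cyp3a41a and Gm1821 were lower. Rpph1, the RNA of ribonuclease P, was higher by 9.74 ± 1.86, Rmrp, the RNA of a related ribonuclease, by 9.44 ± 1.96, the small nucleolar RNA gene Snord17 by 7.85 ± 1.68 and Rn45s by 7.06 ± 1.01. The vault RNA gene Vaultrc5 had 1 count in fresh-frozen libraries and a ratio of 932 (95% counting interval 166 to 36930). Dmbt1, a glycoprotein of mucosal epithelia, had 0 counts in fresh-frozen control livers and was at least 4585-fold higher in FFPE 18 h over the group, but its 4 libraries ranged from 0.825 to 170 CPM. Without FFPE 18 h control animal 06 the values were 7.17 for Rpph1, 6.60 for Rmrp, 5.46 for Snord17, 5.52 for Rn45s and 6.80 on the log2 scale for Vaultrc5. Nrp was higher by 7.63 ± 0.40 and 9530091C08Rik by 6.25 ± 0.57. Cyp3a41a had 2 counts in FFPE 18 h and a ratio of 472 (95% counting interval 131 to 3902) in favour of fresh-frozen, and the pseudogene Gm1821 had 2 counts and a ratio of 428 (118 to 3532). Both share their transcript end with other genes. Lower too were the glucuronosyltransferase genes Ugt3a1 at -4.68 ± 0.22 and Ugt1a9 at -4.78 ± 0.46, whose transcript end is shared within its family, the isoprenoid enzyme Idi1 at -4.65 ± 0.36, Spata5l1 at -5.30, Gm8909 at -4.63, and Echdc1 at -5.13, whose end overlaps a gene on the opposite strand.

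Of 13034 genes tested, 4463 were higher and 4404 lower in FFPE 18 h than in fresh-frozen control livers (4 against 3), and 4693 differed at least 2-fold. The groups did not overlap for 8785 genes (67.4%, where chance gives 5.71%). The count of 8867 was 9425 with the animal as a block and 5769 in 1 model of all 6 groups. DESeq2 gave no adjusted p for Rpph1, Vaultrc5, Rmrp, Snord17 and Rn45s, and Dmbt1 did not pass with robust dispersions. None of the fixed lists passed (limma camera). Secreted proteins went both ways, with the apolipoproteins Apoc1 at 3.95 ± 0.10 and Apoa2 at 3.00 ± 0.10, the thyroid hormone carrier Ttr at 2.74 ± 0.09 and apolipoprotein Apob at -1.44 ± 0.13. In that list of 15 hepatocyte secreted proteins 8 were higher and 3 lower, 8 and 4 adjusted over the list alone (list adjusted p = 0.179). Alb stood at -0.26 ± 0.09, which did not pass in the paired fit with the animal as a block (adjusted p = 0.0950), Gstm1 at 1.85 ± 0.10, Cyp2e1 at -0.44 ± 0.10, Nqo1 at 0.68 ± 0.15 and Cdkn1a at 1.41 ± 0.28. Of the 14 reference genes, 7 were higher and 3 lower, the same adjusted over the list alone, with Sdha of the respiratory chain at -0.56 ± 0.08.

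In FFPE 3 wk control livers Rpph1, Rmrp, Snord17 and Vaultrc5 were again higher than in fresh-frozen ones, and Ttn was high in 2 of 4 animals. Rpph1 was higher by 8.61 ± 0.73, Snord17 by 8.15 ± 1.11, Rmrp by 8.10 ± 1.43, Snord15b by 7.34 ± 1.35 and Gm9159 by 7.16. Snora74a had 0 counts in fresh-frozen libraries and was at least 285-fold higher, and Vaultrc5 had 1 count and a ratio of 2046 (95% counting interval 366 to 80980). Titin (Ttn), the giant spring protein of striated muscle, was higher by 7.35 ± 1.62, with 134 CPM in control animal 03 and 14.9 CPM in control 06 against 4.09 and 2.77 CPM in the other 2. Cyp3a41a, the carboxylesterase Ces2c and the ribosomal protein gene Rpl35 had 0 counts in FFPE 3 wk control livers and were at least 195-fold, 91.6-fold and 87.0-fold lower there. BC005764 had 2 counts and a ratio of 101 (27.9 to 837), and Sprtn, a protease for protein-DNA crosslinks, had 3 counts and a ratio of 111 (37.8 to 537). Gm1821 stood at -5.86 ± 1.25, Ugt1a6a at -5.58 ± 1.03 and Mup7 at -5.51 ± 1.33, and Gm1821 and Mup7 belong to families of near-identical copies. The ends of Snora74a, Snord15b and Rpl35 are shared with other genes in full and that of Rpph1 overlaps another gene, so their levels are uncertain. The same goes for Ces2c, with 73.1% of its transcript shared, and for Ugt1a6a, which overlaps 7 other genes and has 42.73% of its transcript shared.

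Of 12145 genes tested, 1605 were higher and 1583 lower in FFPE 3 wk than in fresh-frozen control livers (4 against 3), with no overlap for 5299 genes (43.6%, where chance gives 5.71%). The count of 3188 was 1978, 2004 and 1988 without fresh-frozen control animals 02, 04 and 06, 2816 with the animal as a block, 6028 in 1 model of all 6 groups, and 5905 without the 2 control libraries with most muscle transcripts, an alternative chosen after seeing the data. Sprtn did not pass without any 1 of the 3 fresh-frozen libraries, and Mup7 did not pass without fresh-frozen control 02 or without those 2 libraries. Urea cycle and amino acid catabolism genes were lower in 8 of 18 cases, and 9 were lower and 1 higher adjusted over the list alone. The urea cycle entry enzyme Cps1 stood at -1.57 ± 0.12 (adjusted p = 0.00253, and adjusted p = 0.921 with an estimated correlation). Bile acid genes were lower in 8 and higher in 2 of 17 cases, the same adjusted over the list alone, with the phospholipid exporter Abcb4 at -1.80 ± 0.15 (adjusted p = 0.0333, and adjusted p = 0.869 with an estimated correlation). With the animal as a block, lipogenesis genes (lower, adjusted p = 0.0494), macrophage markers (higher, adjusted p = 0.0148) and reference genes (higher, adjusted p = 0.0148) also passed. Without the block their adjusted p was 0.0675, 0.257 and 0.0521, and adjusted p = 0.869, 0.921 and 0.869 with an estimated correlation, which was not run with the block. The complement gene C1qc of macrophages was higher by 2.57 ± 0.36 and the cytoskeletal actin Actb by 2.24 ± 0.17. Alb was lower at -0.88 ± 0.07 and Cyp2e1 at -1.03 ± 0.08.

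Between the FFPE pieces of control livers, most listed secreted hepatocyte proteins were lower after 3 wk than after 18 h, and summed muscle genes, of those under 1 CPM in fresh-frozen controls, were higher in animals 03 and 06 and lower in 02 and 04. Of 15 secreted proteins 12 were lower, 13 adjusted over the list alone, with apolipoprotein Apoa1 at -1.25 ± 0.08 and Alb at -0.61 ± 0.07 (adjusted p = 3.04e-14, and adjusted p = 0.464 with an estimated correlation). Urea cycle and amino acid catabolism genes were lower in 7 of 18 cases, 10 adjusted over the list alone, with Asl at -1.16 ± 0.16 (adjusted p = 0.00113, and adjusted p = 0.699 with an estimated correlation). Ttn was higher by 5.78 ± 1.24 and muscle glycogen phosphorylase (Pygm) by 2.79 ± 0.65, and neither passed without the 2 control libraries with most muscle transcripts. Rgmb, a coreceptor for bone morphogenetic proteins, was higher by 3.61 ± 0.90, the small GTPase gene Arl5b by 2.27 ± 0.51, Pik3r3 by 2.52 ± 0.68, Afap1 by 2.46 ± 0.68, Gpc6 by 2.29 ± 0.65 and Pcyox1l by 2.26 ± 0.58. The DNA glycosylase gene Nthl1 had 0 counts after 3 wk and was at least 85.7-fold lower. In furan livers it was less low, at 0 to 4.192 CPM after 3 wk and 5.101 to 7.246 CPM after 18 h. Sec62, of protein import into the endoplasmic reticulum, stood at -2.71 ± 0.13 and Srek1ip1, a splicing partner, at -3.03 ± 0.31. Eif5b, a translation factor whose transcript end overlaps a gene on the opposite strand, stood at -2.49 ± 0.16, Sox4 at -3.75, Trmu at -2.65, Polr2i at -2.58 and Acyp1 at -2.39. Of 12242 genes tested, 523 were higher and 769 lower (4 against 4), with no overlap for 2520 genes (20.6%, where chance gives 2.86%). The count of 1292 was 673, 682 and 720 without FFPE 18 h control animals 02, 03 and 04, 2029 without FFPE 3 wk control 06, 2147 by DESeq2, 3477 in 1 model of all 6 groups, 487 in the 3 control animals used fresh-frozen and 2438 without the 2 control libraries with most muscle transcripts. In the paired fit with the animal as a block the count was 1240, and Pik3r3, Afap1, Gpc6, Acyp1, Rgmb, Pygm, Pcyox1l and Trmu did not pass. Nthl1, Srek1ip1, Sec62 and Eif5b passed under every alternative run, and Ttn, Arl5b, Sox4 and Polr2i did not pass in the 3 control animals used fresh-frozen (adjusted p = 0.107, 0.0674, 0.134 and 0.141).

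**Figure D4:**
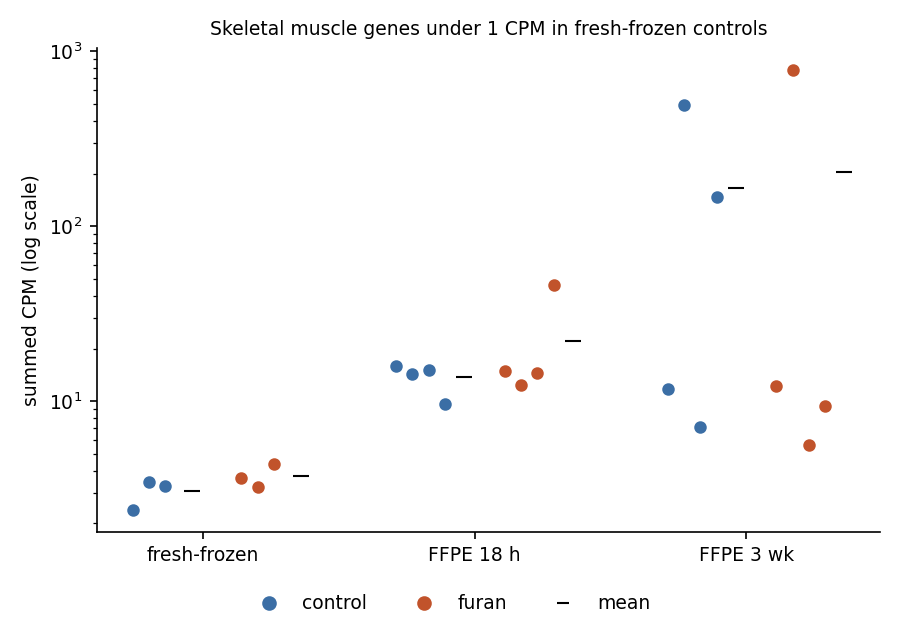
Summed level in CPM (log axis) of listed skeletal muscle genes under 1 CPM in fresh-frozen controls, in each of the 22 libraries (points), by preservation and treatment. The sum is 494.2 CPM in control animal 03, 146.5 CPM in control 06 and 784.4 CPM in furan 42 of FFPE 3 wk.

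Short transcripts were higher and long transcripts lower in FFPE than in fresh-frozen control livers. In the shortest of 5 length bins (median 1391 nt) the median log2 fold change of FFPE 18 h against fresh-frozen was 1.23, and in the longest (median 6738 nt) it was -0.71. FFPE 3 wk gave 0.83 and -0.52. Across genes, Spearman's rho of the fold change with transcript length was -0.550 for FFPE 18 h (12952 genes) and -0.406 for FFPE 3 wk (12081 genes), and with GC content it was 0.252 and 0.150. FFPE 3 wk against FFPE 18 h had the opposite trend, with rho 0.264 for length and -0.170 for GC content. The furan fold change had a rho with length of 0.0588 in fresh-frozen, -0.0453 in FFPE 18 h and 0.12 in FFPE 3 wk livers.

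**Figure D5:**
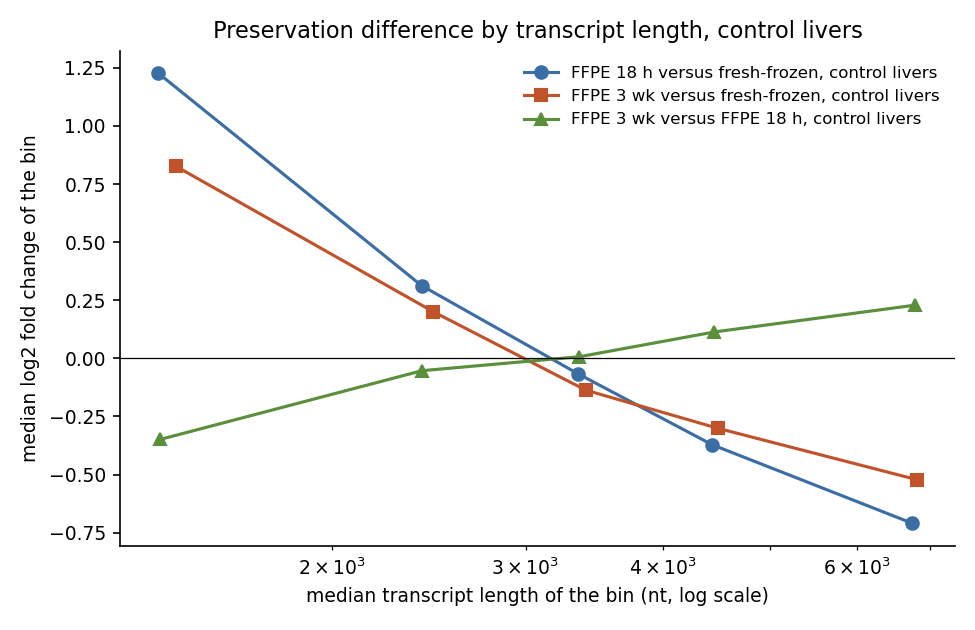
Median fitted log2 fold change (y axis) against median transcript length in nt (x axis, log scale) for 5 bins of genes in each of the 3 preservation comparisons of control livers. The median of FFPE 18 h against fresh-frozen goes from 1.23 in the shortest bin to -0.71 in the longest.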

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

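The tests of shared transcript ends, of depth, of smaller fold changes, of few molecules, of the restricted muscle list and of furan as the source of muscle transcripts were chosen only after the result was seen, and the tests of transcript length, of the muscle list, of the animals over the full list and all splits of the samples were planned.

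Samples far from the other 3 of their group, by the gap to the nearest sample over the range of the group, were found in 5 of 28 library measures and in 30 of 209 sets of named-gene levels, where chance gives about 1 in 20. Control animal 06 of FFPE 18 h was highest in the share of its 10 leading genes (0.975, 51.55% against 26.63% in the nearest library), of Rn45s (0.974, 37.3% against 7.217%) and of microRNA genes (0.959), and lowest in that of cytosolic ribosomal protein genes (0.926, 0.3247%). These are shares of total counts, Rn45s included, so its high share raises that of the leading genes, lowers the others and leaves them not independent. The same library was highest in Rpph1 (0.975), Vaultrc5 (0.980), Rmrp (0.981), Snord17 (0.950), Rn45s (0.974), Arl5b (0.839) and Cyp3a41a (1, with the 2 counts of its group), and control animal 04 of FFPE 18 h was highest in Srek1ip1 (0.938). Among furan livers of FFPE 18 h, animal 41 was lowest in Rad51b (0.914), 44 highest in Ccnd1 (0.870) and 42 highest in Cux2 (0.835).

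In FFPE 3 wk control livers, animal 02 had the lowest total counts (0.887) and the highest Mup20 (0.964), Adrb3 (0.871), AW549542 (0.944) and Sprtn (1). Animal 03 was highest in Prc1 (1, on 1 count), Vaultrc5 (0.878) and Ttn (0.907), animal 04 in Mmp12 (0.980), Atf3 (0.841), BC005764 (1), Gm1821 (1), Mup7 (0.928) and Sox4 (0.906), and animal 06 in Dusp8 (0.935), Gpc6 (0.832) and Arl5b (0.866). Among FFPE 3 wk furan livers, animal 42 was lowest in Tubb2a (0.862) and highest in Cux2 (0.901), and animal 41 was highest in Tnfrsf12a (0.847). Where all counts of a group lie in 1 library the gap is 1 by construction.

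Skeletal muscle transcripts stood high in 3 of the 8 FFPE 3 wk libraries. The summed level of muscle genes under 1 CPM in fresh-frozen controls was 494.2 CPM in control animal 03, 146.5 CPM in control 06 and 784.4 CPM in furan 42, against 5.648 to 12.2 CPM in the other 5. Of 32 muscle genes listed before the test, none of them among those first noticed, 31 had their highest level in 1 of these 3 libraries (96.9%, where 37.5% is expected, one-sided binomial p = 1.271e-12 across genes, which are not independent), so muscle in the sections is a candidate explanation. A lasting difference between the animals was tested on the FFPE 18 h pieces of the same animals: over the full list they held up to 30.69% of the FFPE 3 wk level, which decides nothing because 3 of the 32 genes reach 1 CPM in fresh-frozen controls, and over the other genes at most 6.585%, against such a difference. Furan is argued against by the 2 control livers among the 3 libraries.

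Genes at least 8-fold lower in FFPE than in fresh-frozen control livers were weighed next. Of 98 such genes in FFPE 18 h, 34.69% had a transcript end shared with another gene, against 7.492% of other genes (Fisher p = 1.655e-14), and of 126 in FFPE 3 wk 30.95% had one, against 7.302% (p = 7.5e-15). Reads lost to shared ends may therefore account for that part. The other 62.24% and 65.87% had under 10% of the end shared, so this measure shows no such loss for them. It covers only the last 300 nt of 1 transcript per gene, in a later annotation than that of the counts, so sharing elsewhere stays open. Ugt1a6a in FFPE 3 wk, for instance, had 0% of its end but 42.73% of its transcript shared. After the median of each of 20 length bins was removed, 69 and 112 genes were still at least 8-fold lower. The length trend is small beside an 8-fold fall, so few genes could leave the set and this test decides little. In a comparison that was not planned, the genes had a median length of 3336.5 nt (FFPE 18 h) and 3290.5 nt (FFPE 3 wk). Other genes had 3350.5 and 3403 nt, which argues against transcript length as the whole cause. No biological explanation was tested, and the extraction kit cannot be told apart from preservation.

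Furan changed fewer genes past the threshold in FFPE 3 wk (99) than in fresh-frozen livers (2162). Common dispersion was larger in FFPE 3 wk, at 0.336 against 0.0150, and at 0.1869 against 0.01165 after thinning. Depth as the whole cause is argued against, since fresh-frozen libraries thinned to the shallowest total still gave 759 genes. Smaller fold changes are argued against only for genes that changed at least 2-fold in fresh-frozen livers. The 160 that rose had a median of 1.454 there and 1.468 in FFPE 3 wk, and the 50 that fell had -1.171 and -1.125. Most of the 1997 fresh-frozen genes tested in both changed less than 2-fold, and for them smaller fold changes stay open. Few distinct molecules per library remain a candidate explanation: 8 of 8 FFPE 3 wk libraries had fewer genes with 1 to 9 counts (544 to 2457) than every thinned fresh-frozen library (3040 to 3687). The same held for 7 of 8 FFPE 18 h libraries (2080 to 3864 against 2924 to 3275), where 1077 genes passed and 697 after thinning, so this sign alone does not account for the fewer genes. The muscle transcripts of 3 libraries stay open as a further source, with 53 genes without those libraries.

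Other splits of the samples gave at most 0 genes for furan in FFPE 18 h (real 1077, 35 splits) and at most 2 in FFPE 3 wk (real 99, 35 splits). Only the real split, 1 in each, gave as many, a share under 0.05, so chance is unlikely for both but not excluded. The same holds for the correlation of FFPE 18 h and FFPE 3 wk responses (0.392, highest other 0.228 of 35). The other splits mix furan and control animals, which adds the furan difference to the spread within their groups. The splits are too few for a share under 0.05 in fresh-frozen livers (2162, highest other 1 of 10), in the 3 preservation comparisons (8867, 3188 and 1292, highest other 0 among the 8 splits that part as many pairs), in the 2 differences between furan responses (0 and 0, where all 20 splits gave as many, highest other 0 and 1), and for the correlations of fresh-frozen with FFPE 18 h (0.735, highest other 0.519 of 20) and with FFPE 3 wk (0.426, highest other 0.258 of 20). Over all 35 splits of FFPE 18 h and fresh-frozen controls, placing FFPE 18 h control 06 with the 3 fresh-frozen libraries gave 2360 genes, which points to a structure of the samples.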

How the results depend on the processing

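The fits on the 6 animals used fresh-frozen, without the libraries with most Rn45s, without the shallowest libraries and without the libraries with most muscle transcripts, and the omission of animals from the correlation, list and length results, were chosen only after the data were seen, and all other alternatives were planned.

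For each result that changed, the cause was not tested except where the alternative itself uses fewer libraries, fewer counts or a stricter threshold. Over 253 named-gene results and 4462 alternative values, 4041 (90.6%) kept their side of the threshold, 367 lost it and 54 gained it. With either fit passing, 0 turned direction, while turns with neither fit passing were counted as kept. Over 165 list results and 855 values the numbers were 773, 51, 31 and 0. For lists a turn was counted only where both fits passed, so smaller turns of direction were not counted. Asking for at least 1.5-fold left 790 furan genes in fresh-frozen and 440 in FFPE 18 h. One model of all 6 groups gave 138, 225 and 2030 furan genes in fresh-frozen, FFPE 18 h and FFPE 3 wk, 5769, 6028 and 3477 genes for FFPE 18 h against fresh-frozen, FFPE 3 wk against fresh-frozen and FFPE 3 wk against FFPE 18 h, and 19 for the difference of the FFPE 3 wk and fresh-frozen responses. That model shares its dispersions among all groups, with a common dispersion of 0.133. The separate furan fits had 0.0150, 0.0284 and 0.336, so the model understates the spread of FFPE 3 wk and overstates that of the other 2. Thinning gave 759 in fresh-frozen and 697 in FFPE 18 h. DESeq2 gave 371 furan genes in FFPE 3 wk, 2147 for FFPE 3 wk against FFPE 18 h, and 1 and 38 for the differences of FFPE 18 h and FFPE 3 wk from fresh-frozen responses. No filter on low counts gave 194 in FFPE 3 wk. The 6 animals used fresh-frozen gave 594 in FFPE 18 h (417 thinned), 19 in FFPE 3 wk (21 thinned) and, with the 3 control animals among them, 487 for FFPE 3 wk against FFPE 18 h. Without the shallowest libraries FFPE 3 wk had 12 furan genes and 2 for the difference, and without those with most muscle transcripts 53, with 5905 and 2438 for FFPE 3 wk against fresh-frozen and FFPE 18 h. The replicate block, a paired fit, gave 2 genes for the FFPE 18 h difference and 5 lists for FFPE 3 wk against fresh-frozen. With an estimated correlation 2 lists passed in each of the 3 furan comparisons and 0 in FFPE 3 wk against fresh-frozen and against FFPE 18 h. Among genes of at least 5 CPM the correlations of furan responses were 0.832, 0.557 and 0.549 (fresh-frozen with FFPE 18 h, with FFPE 3 wk, and FFPE 18 h with FFPE 3 wk), and in fits on part of the animals 0.519, 0.256 and 0.205 with different and 0.628, 0.305 and 0.243 with the same animals, while the rank correlation with length was -0.597 and -0.466 for the 2 FFPE times against fresh-frozen and that with GC content 0.271 for FFPE 18 h.

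No paired fit was possible within 1 preservation because control and furan animals share no number. With 1 library left out, furan counts ran from 864 to 1620 in fresh-frozen, from 633 to 1285 in FFPE 18 h and from 17 to 173 in FFPE 3 wk. The preservation counts ran from 8111 to 9299, from 1978 to 4398 and from 673 to 2029, and the lists from 10 to 15, 10 to 15 and 10 to 13 in the 3 furan comparisons. The differences of responses ran from 0 to 0 and from 0 to 5 in the unpaired edgeR fit. With all libraries 455 and 590 genes had an unadjusted p under 0.05 in that fit, both below a share of 0.05. In the paired fit 1559 and 741 had one, both above that share. The correlations ran from 0.685 to 0.719, from 0.314 to 0.396 and from 0.278 to 0.359. The rank correlation with length ran from -0.560 to -0.537, from -0.415 to -0.381 and from 0.223 to 0.309, and with GC content from 0.243 to 0.260, from 0.138 to 0.161 and from -0.188 to -0.136. On simulated data, which do not separate depth from spread, 20.6% of 2-fold changes and 61.7% of 4-fold changes were recovered in FFPE 3 wk, against 73.8% and 98.4% in fresh-frozen livers. Thinning FFPE 3 wk libraries to the shallowest total gave 114 furan genes against 99.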

Other observations

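The gene groups and single genes in this part, and the tests on them, were chosen only after their values were seen.

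Tubulin genes, which encode the subunits of microtubules, rose with furan in 7 of 11 cases in fresh-frozen livers, with Tubb2a at 2.33, Tubb4b at 1.45 and Tuba1c at 0.99 (n = 3 and 3, list median 0.67). The group passed at adjusted p = 8.30e-12 (adjusted p = 0.134 with an estimated correlation). In FFPE 18 h 6 of 11 rose (adjusted p = 5.03e-12, and adjusted p = 0.0735 with an estimated correlation) and in FFPE 3 wk 1 of 10 (adjusted p = 0.00259, and adjusted p = 0.175 with an estimated correlation). Genes chosen by the symbols of proteasome subunits, which degrade tagged proteins, showed 1 rise among 39 (with Psmc3ip, which is not a subunit) in fresh-frozen livers, Psmd5 at 0.38 (adjusted p = 0.0103, and adjusted p = 0.729 for the group), 1 rise and 1 fall among 38 in FFPE 18 h, and 0 of 37 in FFPE 3 wk (edgeR). Genes higher in female liver rose in 5 and fell in 3 of 18 cases in fresh-frozen livers, 5 and 4 of 17 in FFPE 18 h and 1 and 0 of 16 in FFPE 3 wk. Genes higher in male liver rose in 2 cases (Mup20 and Gstp1, the latter at 0.51) and fell in 1 (Elovl3 at -2.51) of 18 in fresh-frozen livers, 2 and 4 of 15 in FFPE 18 h, and 1 and 1 of 15 in FFPE 3 wk (adjusted p = 0.0234, and adjusted p = 0.488 with an estimated correlation).

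Fbf1 differed between furan animals in the same order in each preservation. It stood at 171.6, 104.7 and 62.08 CPM in fresh-frozen animals 41, 43 and 44, at 151.7, 104.7 and 62.39 CPM in FFPE 18 h and at 178.8, 119.1 and 67.91 CPM in FFPE 3 wk. Animal 42, which was not used fresh-frozen, had 28.49 and 42.6 CPM of Fbf1 in its FFPE pieces, and 41.95 and 48.14 CPM of Cux2, where the other furan animals had at most 11.54 CPM of Cux2 in FFPE pieces. The FFPE 18 h piece of furan animal 44 held 46.2 CPM of muscle genes under 1 CPM in fresh-frozen controls, where the other 7 pieces of that preservation held from 9.645 to 15.89 CPM. Dmbt1 ranged from 0.8248 to 170.2 CPM among FFPE 18 h control livers and from 0.206 to 29.9 CPM among FFPE 3 wk control livers.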
